A study of Mus musculus with 6 samples.

How the data were processed

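Expression was measured in islets of 3 NZO and 3 B6-ob/ob samples, 1 array per sample, on Agilent mouse arrays of design 014868. Per the labels, total RNA was amplified to cRNA with the Cy3 dye and each array holds 1 colour. The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction 10.5.1.1 per the file headers, while the submitters' processing notes name version 9.1. The processed intensity in these files was background-subtracted and detrended within the array by that software, per the file headers, and was not normalised between arrays. The authors' value table, which holds processed intensities of the same arrays at 33150 probes, was used as an alternative. Its columns are linear, not centred and nearly equal after sorting (largest gap 0.189 on the log2 scale), as after quantile normalisation, a step not given in the sources used here. The medians of its columns are 21.3, 21.4 and 21.5 for those labelled NZO 10, 11 and 12, and 22.1, 21.4 and 22.4 for those labelled B6-ob/ob 4, 5 and 6. Of its rows 33074 matched a probe of the scanner files. Its scale and centring were settled from this comparison, but its direction was not, because each column follows an array of the other strain.

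The groups were taken from the labels of the scanner files. Control spots were left out and between 61 and 76 flagged spots per array were treated as missing. No probe was saturated. The log2 of the processed intensity was averaged over the spots of a probe and then lowered by each array's 75th percentile over 41174 non-control probes. A probe was kept if the scanner software called it well above background on at least 3 of 6 arrays, which left 24628 of 41174 probes. Each gene name of the files was represented by its brightest kept probe, and 50 updated symbols stand on several such names, which were tested apart. Names came from the files, updated through a table of RefSeq accessions and symbols: 25097 probes were named through their accession, 7973 through a symbol or synonym, and 8104 kept the file's name. Positions are those of the files, on mm9.

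Strains were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 16418 genes and a threshold of 0.05. Gene lists were compared with camera, a competitive test against all other genes, with a preset correlation of 0.01 between genes, over lists with at least 5 measured members. An estimated correlation and the rotation test fry stand beside it. The test, the 43 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the 10 highest and 10 lowest differences among called genes measured on all 6 arrays without overlap of the strains, and the 3 greatest bounds in each direction among probes measured in 1 strain only. It also names up to 3 called members of each list that was called or had at least 3 called members, and Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mki67, Txnip, Lep and Nnt. Clones, predicted genes and unnamed probes were left out, and some genes that the rule names are not reported. Ghrl, Insm1, Scg2, Neurog3, Ctrb1, Krt19, Sox9, Aldh1a3, Gpd1, Klf10, Il6, Cxcl1, Ier3, Mx1, Ccnd2 and Cdk6 were named after their values were seen. Of the alternatives 3 were added after seeing the data.

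The functions were tested on simulated data with the means and spreads of the 16418 genes of this comparison, some of them changed. Of 67, 67 and 66 genes changed by 1, 2 and 3 on the log2 scale, 44.8%, 85.1% and 93.9% were recovered, and 3 of 16193 unchanged genes were called. Far fewer genes were changed here than the 3643 called in the data. Recovery under this adjustment depends on the share of changed genes, so these rates do not carry over to the data. In these simulated arrays genes vary independently, so they do not test how camera behaves where genes vary together. The alternatives covered background and normalisation, the value table, the filter on dim probes, the gene summary, slide, the prior variance, array weights and each array left out.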

Results

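Pancreatic islets of 2 obese mouse strains were compared on 1-colour oligonucleotide arrays, which read the abundance of transcripts as the brightness of a Cy3 dye at each probe. NZO/HiBomDife mice (New Zealand Obese, here NZO) are labelled diabetes-prone, and C57BL/6.V-Lepob/ob mice (here B6-ob/ob), which lack functional leptin, are labelled diabetes-resistant. All animals were male. They had eaten a fatty diet without carbohydrate up to 18 weeks of age, and their islets were taken 48 h after carbohydrate was added to the diet. Each strain has 3 arrays, NZO replicates 10, 11 and 12 and B6-ob/ob replicates 4, 5 and 6, and each array holds 1 labelled sample. The labels do not say whether a sample is 1 animal or a pool, so p-values measure the spread between these samples, which may be technical. Between 23621 and 24711 of 41174 probes were well above background on each array, and the number of arrays limits the precision. No islets from before the diet change were analysed here, so each value compares the strains at 1 time and not the response to carbohydrate.

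The comparison asks which transcripts differed between islets of the diabetes-prone and the diabetes-resistant strain. Exocrine enzymes such as Ctrb1 and matrix genes such as Fbn1 were higher in NZO, by 2.89 and 2.47 on the log2 scale, as was Cck at 6.88. Ckap4 at -6.34 and Folr1 at -6.12 were lower, and the insulin genes Ins1 and Ins2 differed by 0.07 and 0.06. All signed values here are NZO minus B6-ob/ob by the labels of the scanner files, and their direction opposes that of the deposited value table. Of 16418 genes or unnamed probes tested with limma, 3643 differed at an adjusted p under 0.05, with 2165 higher and 1478 lower in NZO. Of these, 1438 were higher and 602 were lower by at least 1 on the log2 scale. The 3 arrays of one strain lay wholly above or below those of the other at 6748 genes, against 10% expected by chance for 3 against 3 arrays. Pearson's r over genes was 0.9853 to 0.9894 between NZO arrays, 0.9681 to 0.9872 between B6-ob/ob arrays and 0.9281 to 0.9479 between strains, and genes are not independent replicates. All 6 columns of the value table follow an array labelled with the other strain. For this match each probe was first centred on its mean over the 6 arrays, in each source. The r over centred probes was between 0.966 and 0.984 with that array, and between -0.523 and -0.778 with the array of the column's own label. Ifi202b and H2-Ea, which B6-derived mice are known not to express, were well above background on the 3 scanner arrays labelled NZO and on no array labelled B6-ob/ob. The order of the columns in the value table gives the opposite. There Ifi202b stood at 1.12 to 1.16 in columns labelled NZO and at 7.92 to 9.30 in those labelled B6-ob/ob, on the log2 scale. These 2 genes argue against swapped labels in the scanner files, although no source used here states which labels are wrong.

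Among the greatest excesses in NZO of genes measured on all 6 arrays was that of Cck, which encodes the gut hormone cholecystokinin. Its level was 4.60 ± 1.87 (SD, n = 3) in NZO and -2.28 ± 1.15 in B6-ob/ob, in log2 units relative to each array's 75th percentile, a difference of 6.88 with a standard error of 1.02 (limma adjusted p = 0.0057). The tight junction gene Cldn11 was higher by 6.68, the muscle and stress response gene Ankrd1 by 5.58 and Angptl7 by 5.21. Enpp1, an ectoenzyme that binds the insulin receptor, was higher by 5.18, Itih1 by 4.95, the keratin gene Krt23 by 4.95, the trypsin inhibitor gene Spink1 by 4.81 and the lymphotoxin gene Ltb by 4.80. The Cck probe lies on chromosome 9 at 121399031 to 121399090 of mm9, the build of the probe positions in the files, which do not say which part of a transcript a probe covers. The greatest deficit in NZO on all 6 arrays was that of Ckap4, which encodes a membrane protein of the endoplasmic reticulum. It fell from 3.08 ± 0.48 in B6-ob/ob to -3.25 ± 0.35 in NZO, a difference of -6.34 with a standard error of 0.29 (limma adjusted p = 0.00014), by a probe on chromosome 10 at 83990203 to 83990262. The folate receptor gene Folr1 was lower by the difference -6.12 and the ciliary gene Ttc8 by -4.81, followed by Trmt61b at -4.00, Fggy at -3.97, Rab6b at -3.58, Nrcam at -3.53, Prdm16 at -3.49 and Cpne4 at -3.46. A probe named Gja5, on chromosome 3 at 98214966, differed by -3.70, while another kept probe of that name, at 96857349, was higher in NZO by 3.56. Which of them measures Gja5 was not settled.

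**Figure D1:**
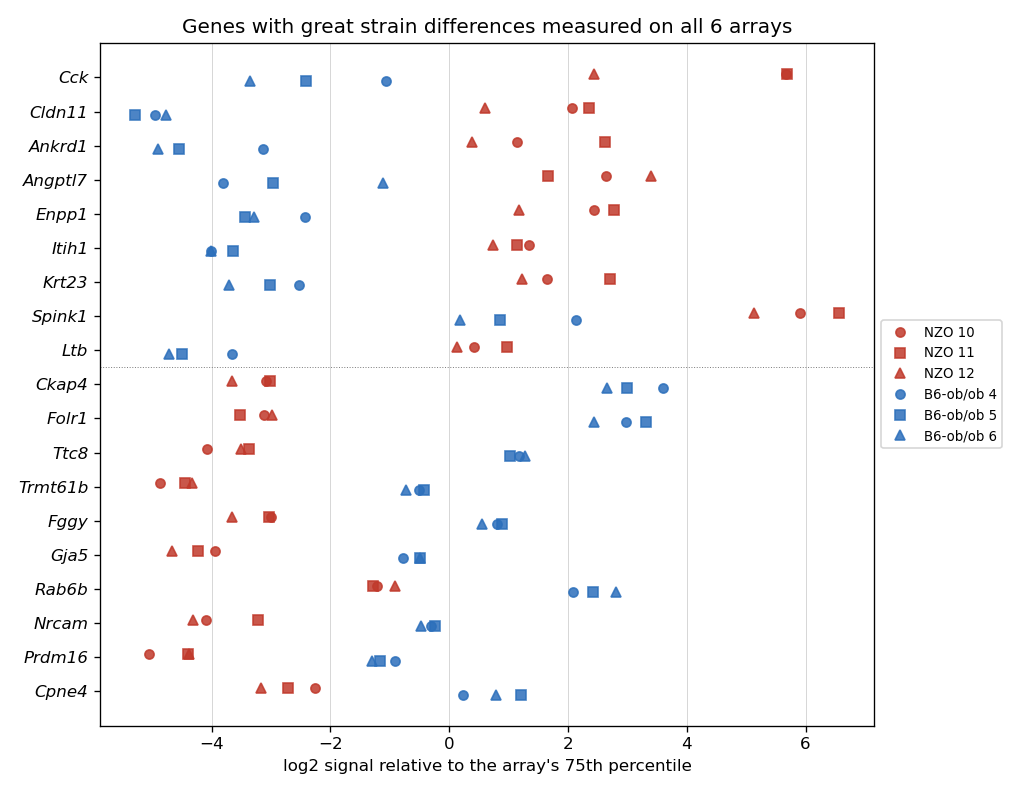
Level of genes with great strain differences on each array, on the x axis as log2 signal relative to the array's 75th percentile, with NZO arrays in red and B6-ob/ob arrays in blue and 1 symbol per replicate. The genes above the dotted line were higher and the 10 below it lower on all 3 NZO arrays, from a difference of 6.88 for Cck to -6.34 for Ckap4.

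Some probes were well above background in 1 strain only, and their fold is a lower bound, in which a dim array stands at its lowest signal well above background or at the probe's own signal, whichever is higher. Aldh1a7, a retinaldehyde dehydrogenase relative, was at least 104-fold higher in NZO and the interferon-inducible gene Ifi202b at least 46.3-fold, with limma adjusted p of 0.000627 and 0.00014. In the other direction H2-Q1, a class I histocompatibility gene, was at least 513-fold lower in NZO by a probe on chromosome 17 at 35461951 to 35462010. One probe of Thumpd1 was at least 167-fold and 1 of Slx1b at least 125-fold lower, with adjusted p of 2.22e-06 for H2-Q1 and for Thumpd1 and 3.81e-05 for Slx1b. The other kept probe of Thumpd1 was near background, and that of Slx1b, well above background on all 6 arrays, differed by 0.11. Lefty1, a TGF-beta family ligand, was at least 63.3-fold lower in NZO. Lep was not well above background on any array, and its probe would not check the labels, since the ob allele is a point mutation.

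Of the transcripts of islet hormones 1 passed the test. Ins1 and Ins2, the 2 mouse insulin genes, differed by 0.07 and 0.06, glucagon (Gcg) by 0.09 and pancreatic polypeptide (Ppy) by 0.18 on the log2 scale, with limma adjusted p between 0.479 and 0.855. Somatostatin (Sst) differed by -0.54 (adjusted p = 0.0888). Nnt, a mitochondrial enzyme gene known to vary among B6 substrains, differed by -0.02 (adjusted p = 0.955). The stomach hormone ghrelin (Ghrl), 1 of the 7 measured members of the hormone list, was the one that fell in NZO, by the difference -3.01 (adjusted p = 0.00271), so that the list's median was 0.06 and its mean -0.45. Among 22 beta cell identity factors, 4 were lower in NZO and none was higher, or 2 adjusted over the list alone. The 4 were Isl1 at -1.05, Nkx6-1 at -0.81, Foxa2 at -0.89 and Insm1 at -0.54, all transcription factors of endocrine cells, while Pdx1 differed by 0.14 (adjusted p = 0.666). The mean of the 22 factors was 2.15, 2.53 and 2.97 on B6-ob/ob replicates 4, 5 and 6, the reverse of the order of the acinar markers given below. On NZO replicates 10, 11 and 12 it was 2.27, 2.13 and 2.52, which is not the reverse of the acinar order. Whether the content of exocrine tissue lowers these values was not tested. With slide as a block 1 of the 22 was lower, and of 21 tested alternatives Foxa2 kept its call in 8, Nkx6-1 in 12 and Isl1 in 20. By limma's camera test neither list passed (adjusted p = 0.581 and 0.125). The identity factors passed as lower without B6-ob/ob replicate 4 (0.02) and with no filter on dim probes (0.0277). Of 27 genes of the secretion machinery, Kcnj11, a subunit of the ATP-sensitive potassium channel, was lower at -0.68, as were Snap25 at -0.58 and Scg2 at -0.47, and Scg5 was higher at 1.34 (camera adjusted p = 0.395). With each array left out in turn 0 to 2 genes of the list were lower, and of 21 tested alternatives Kcnj11 kept its call in 15 and Snap25 in 14. Among 14 receptors that modulate secretion, the muscarinic receptor gene Chrm3 and the glucagon receptor gene Gcgr were higher at 1.37 and 1.61, and Sstr3 was lower at -0.53 (camera adjusted p = 0.395).

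Markers of the exocrine pancreas were higher in NZO. Of 22 acinar cell markers 20 were higher, with a median difference of 2.52, and adjusted over the list alone the number was also 20 (camera adjusted p = 1.93e-09, and adjusted p = 0.608 with an estimated correlation). They included Ctrb1, a chymotrypsinogen, at 2.89, Reg1 at 2.51, Ptf1a, the acinar transcription factor, at 2.72 although well above background on 1 of 3 B6-ob/ob arrays, and Cpa3, a protease known also from mast cells, at least 2.95-fold. The list's mean was 5.31, 5.55 and 5.96 on NZO replicates 10, 11 and 12, and 4.09, 3.21 and 2.49 on B6-ob/ob replicates 4, 5 and 6. Of 12 ductal markers 6 were higher, among them the keratin gene Krt19 at 4.37, the carbonic anhydrase gene Car2 at 2.71, Onecut1 at 1.56 and Muc1 at least 7.34-fold, or 7 adjusted over the list alone (camera adjusted p = 0.000583, and adjusted p = 0.608 with an estimated correlation). Leaving out B6-ob/ob replicate 5 brought the number of higher acinar markers to 9. With slide as a fixed block it was 10, at a median of 2.25, and with slide as a random block 20.

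Stromal and immune markers were also higher in NZO. Of 16 markers of stellate cells, pericytes and fibroblasts 14 were higher, including the collagen gene Col6a1 at 2.56, the platelet-derived growth factor receptor genes Pdgfrb at 1.26 and Pdgfra at least 5.48-fold, and fibronectin (Fn1) at 4.80 although well above background on 1 of 3 B6-ob/ob arrays, or 15 adjusted over the list alone (camera adjusted p = 1.17e-08, and adjusted p = 0.494 with an estimated correlation). Of 25 genes of extracellular matrix and integrins 17 were higher, with Mmp14 at 2.53, fibrillin (Fbn1) at 2.47 and the laminin gene Lama4 at 1.12, or 21 adjusted over the list alone (camera adjusted p = 1.93e-09, and adjusted p = 0.494 with an estimated correlation). Of 10 lymphocyte markers 8 were higher, or 8 of 18 with no filter on dim probes and 4 of 5 among those above background on all 6 arrays, with Il7r at least 2.09-fold and Cd8b1 at least 1.89-fold, or 10 adjusted over the list alone (camera adjusted p = 1.61e-05, and adjusted p = 0.494 with an estimated correlation). Under normexp and quantile normalisation 3 of the 10 lymphocyte markers were higher, at a median of 0.29 against 1.52. Of 18 macrophage and myeloid markers 7 were higher, with Cd14 at 2.65 and the lysozyme genes Lyz1 at 1.63 and Lyz2 at 1.75, or 8 adjusted over the list alone (camera adjusted p = 0.000472, and adjusted p = 0.695 with an estimated correlation). Of 15 endothelial markers 4 were higher, with Cldn5 at 2.46, Esam at 0.81 and Robo4 at 0.69, and adjusted over the list alone 4 (camera adjusted p = 0.0376, and adjusted p = 0.695 with an estimated correlation). The endothelial call ended with slide as a block (adjusted p = 0.13) and without NZO replicate 10, NZO replicate 12 or B6-ob/ob replicate 6. On B6-ob/ob replicates 4, 5 and 6 the mean of the stellate, pericyte and fibroblast markers was 0.04, -0.74 and -1.15, in the same order as that of the acinar markers. On NZO replicates 10, 11 and 12 it was 1.78, 1.65 and 1.80, which is not the acinar order.

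**Figure D2:**
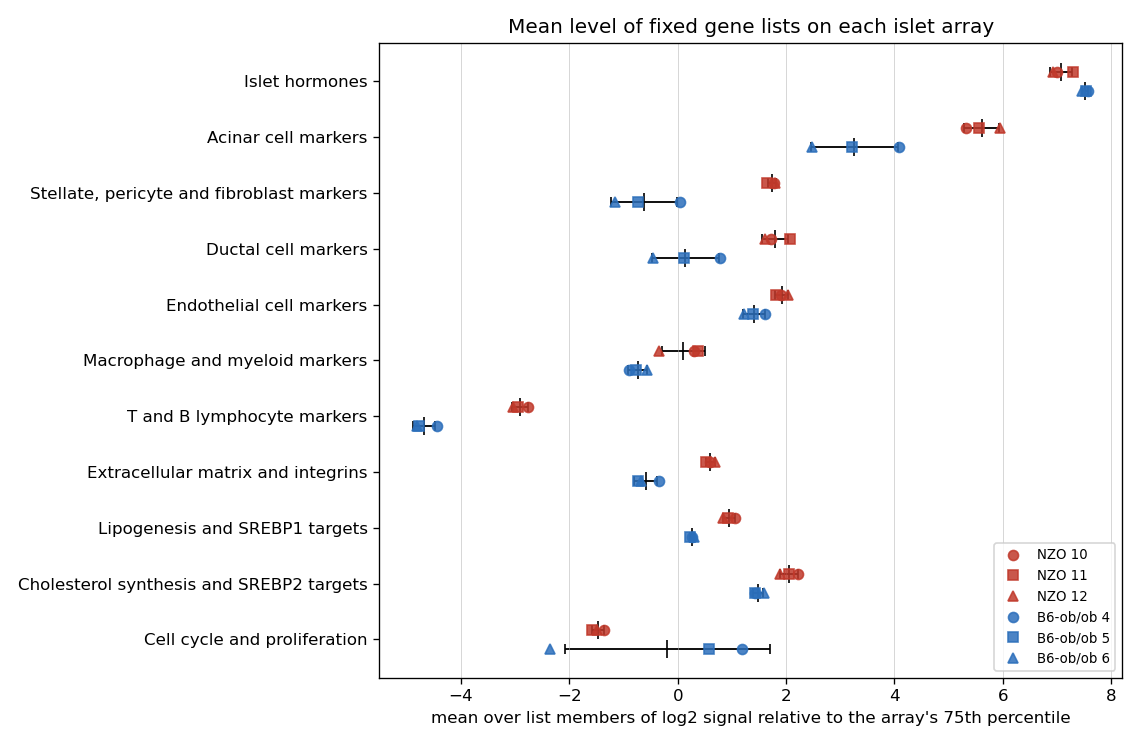
Mean over the measured members of 11 gene lists on each array, on the x axis as log2 signal relative to the array's 75th percentile, with bars for the mean ± SD of the 3 arrays of a strain. Acinar markers lie between 5.31 and 5.96 on the NZO arrays and between 2.49 and 4.09 on the B6-ob/ob arrays, and proliferation genes spread from -2.35 to 1.19 over the B6-ob/ob arrays.

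Proliferation genes were low on all 3 NZO arrays and differed widely among the B6-ob/ob arrays. The mean of 46 cell cycle genes was -1.37, -1.59 and -1.48 on NZO replicates 10, 11 and 12, against 1.19 and 0.59 on B6-ob/ob replicates 4 and 5 and -2.35 on B6-ob/ob replicate 6. Mki67, the usual marker of dividing cells, stood at 2.95, 2.03 and -2.40 on B6-ob/ob replicates 4, 5 and 6 and between -0.59 and -0.25 on the NZO arrays, a difference of -1.32 with a standard error of 1.33 (limma adjusted p = 0.538). In the comparison of all arrays 2 of the 46 genes fell in NZO, the spindle gene Prc1 at -2.95 and the replication licensing gene Mcm2 at -1.30, and none did adjusted over the list alone, with slide as a block or without any one NZO array. The list as a whole was lower, with a median of -1.35 (camera adjusted p = 0.000637, and adjusted p = 0.798 with an estimated correlation). Single B6-ob/ob arrays decided these values. Without B6-ob/ob replicate 6, 41 of the 46 genes were lower in NZO and the median was -2.55, and without B6-ob/ob replicate 4 the call ended, at a median of -0.55 (camera adjusted p = 0.063). Without B6-ob/ob replicate 5 the median was -0.81 (camera adjusted p = 0.0122). Within slide 2 the list's median was -2.80 and within slide 3 it was -0.66. Among 14 cyclin D, CDK and inhibitor genes, the inhibitor gene Cdkn1b was lower in NZO at -1.85, Ccnd1 at -1.15 and Ccnd2 at -0.69, and Cdkn1c at 1.12 and Cdk6 at 0.96 were higher (camera adjusted p = 0.395).

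**Figure D3:**
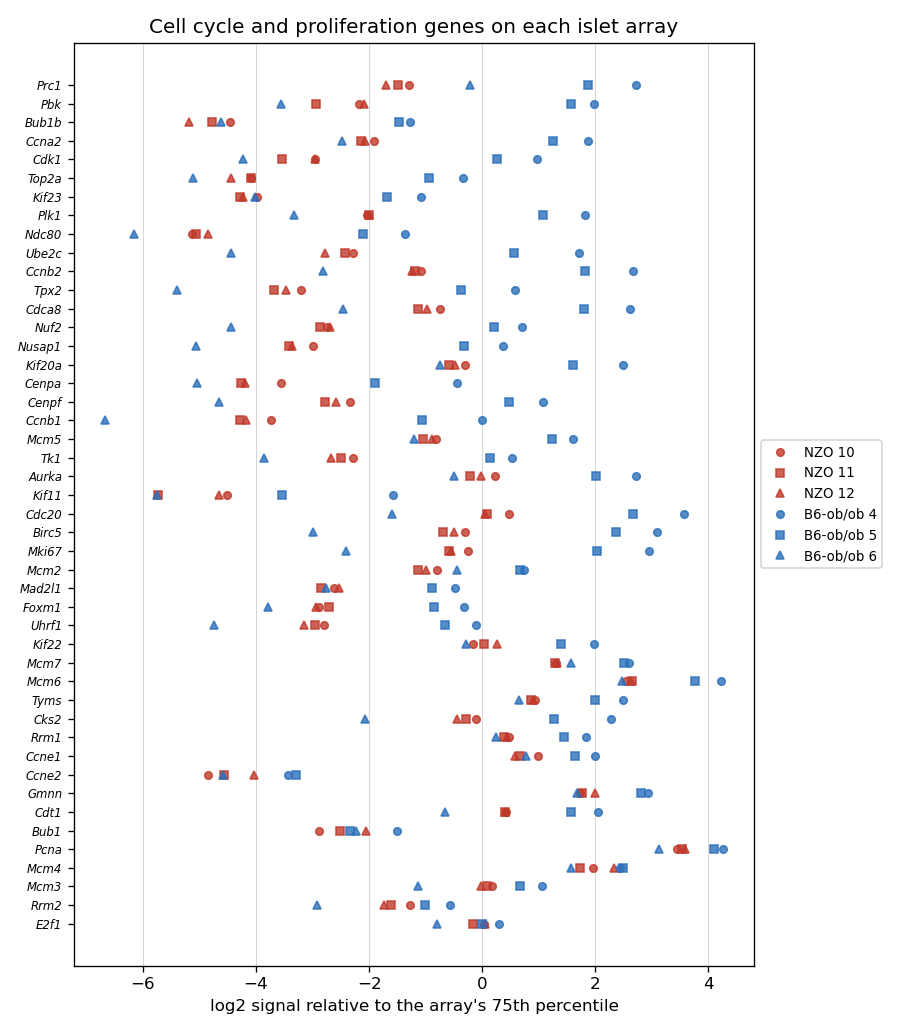
Level of the 46 measured cell cycle and proliferation genes on each array, on the x axis as log2 signal relative to the array's 75th percentile, with NZO arrays in red and B6-ob/ob arrays in blue. B6-ob/ob replicate 6, the blue triangles, lies below B6-ob/ob replicates 4 and 5 at 45 of the 46 genes.

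Some genes of lipid synthesis were higher in NZO, fewer with slide as a block, where 5 lipogenic and 3 cholesterol genes were. Of 19 lipogenic genes and SREBP1 targets 8 were higher, with Pnpla3 at 2.47, the desaturase gene Scd1 at 1.76 and the triglyceride synthesis gene Dgat2 at 1.44, and adjusted over the list alone 8 (camera adjusted p = 0.000336, and adjusted p = 0.494 with an estimated correlation). Of 21 genes of cholesterol synthesis and SREBP2 targets 8 were higher, or 13 adjusted over the list alone (camera adjusted p = 1.61e-05, and adjusted p = 0.602 with an estimated correlation). The probe named Idi1, higher at 1.02, lies on chromosome 2 per the files, and whether it measures that gene was not tested. Fdps was higher at 0.77 on the probe used and differed by -0.18 on its other kept probe. Of 14 targets of the glucose-sensing factor ChREBP 5 were higher, among them the pyruvate kinase gene Pklr at 2.34, Arrdc4 at 1.19, Klf10 at 0.89 and Gpd1, and adjusted over the list alone 5 (camera adjusted p = 0.0378, and adjusted p = 0.494 with an estimated correlation). The ChREBP call ended without NZO replicate 10 (camera adjusted p = 0.0689), without B6-ob/ob replicate 4 (0.0744) and with the mean of each gene's probes (0.0609). Txnip, a target known to rise with glucose in islets, differed by 0.55 (limma adjusted p = 0.344). In the glycolysis list 5 of 24 genes were higher, among them Pfkfb3 at 2.41, Hk2 at 1.06 and Ldha at 1.04 (camera adjusted p = 0.395). In fatty acid oxidation 7 of 23 were higher and 1 was lower, with Acot1 at 1.57, Plin2 at 1.25 and Acadl at -1.40 (camera adjusted p = 0.0903). Under normexp and quantile normalisation this list was called higher (camera adjusted p = 0.0349).

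Of 18 genes that mark dedifferentiation or are normally silent in beta cells, 13 were higher in NZO and 1 was lower, the same numbers adjusted over the list alone (camera adjusted p = 1.61e-05, and adjusted p = 0.557 with an estimated correlation). Cck, Pdgfra, Mgst1 at 2.60, catalase (Cat) at 1.49 and Aldh1a3 at 1.43 were higher, and Neurog3, the transcription factor of endocrine progenitors, was lower at -2.10. Sox9 at 3.62 and Pdgfra also stand among the ductal and the stromal markers. The mean of this list was -0.96, -1.45 and -1.99 on B6-ob/ob replicates 4, 5 and 6, in the order of the acinar and stromal means. On NZO replicates 10, 11 and 12 it was 0.17, 0.28 and -0.09, lowest where the acinar mean was highest. Whether these genes differed in beta cells or in other cells was not tested. Of 25 chemokines, cytokines and NF-kB targets 7 were higher, with Il6 at 4.07, Cxcl1 at 3.53, Cxcl16 at 1.76, Cxcl12 at 1.47 and Tnfaip3 at 1.34, or 12 adjusted over the list alone (camera adjusted p = 4.9e-06, and adjusted p = 0.608 with an estimated correlation). Of 18 immediate early genes 4 were higher, Ier3 at 1.21, Zfp36 at 1.15, Nr4a2 at 0.89 and Junb at 0.77, and adjusted over the list alone 4 (camera adjusted p = 0.0151, and adjusted p = 0.727 with an estimated correlation). The immediate early call ended without B6-ob/ob replicate 4 (camera adjusted p = 0.268), without NZO replicate 12 (0.0639), in the value table (0.0541) and with array weights (0.139). With slide as a block 1 immediate early gene was higher. The mean of the chemokine list was 0.30, -0.88 and -1.39 on B6-ob/ob replicates 4, 5 and 6, in the same order as that of the acinar and of the stromal markers. On NZO replicates 10, 11 and 12 it was 1.52, 1.71 and 0.475, also lowest on replicate 12. The order over the B6-ob/ob arrays is not particular to these lists, since the mean of ribosomal protein genes, at 6.93, 6.61 and 6.27, shares it. Interferon-induced genes went both ways, with 7 of 28 higher and 3 lower, as did histocompatibility genes, with 3 of 22 higher and 3 lower (camera adjusted p = 0.435 and 0.717). The median of the interferon list was -0.11 within slide 2 and 0.55 within slide 3. Mx2 was lower at -3.45 and Mx1 higher at 2.63. Ifi203, well above background on 1 of 3 NZO arrays, was lower at -3.21 on the probe used and differed by 2.76 on its other kept probe. B2m was higher at 1.25, and H2-Ea, a class II chain, was at least 10.4-fold higher in NZO.

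Of 43 lists 42 held enough measured genes to test, and camera called 14, 13 higher and 1 lower in NZO. None was called with an estimated correlation, so the camera calls rest on the preset correlation of 0.01. Other divisions of the 6 arrays into 3 and 3, which mix the strains, called up to 17 lists. Fry uses no preset correlation and does not compare a list with the other genes. Of the lists that camera called, it did not call proliferation (fry adjusted p = 0.345), immediate early genes (0.197), macrophages (0.0928) or endothelium (0.053). The others passed fry, with adjusted p of 0.00388 to 0.0486. Of the lists that camera did not call, fry called cilium genes (fry adjusted p = 0.00638) and the cyclin D, CDK and inhibitor genes (0.0288) lower. It called apoptosis (0.00234), fatty acid oxidation (0.0184), neuron and glia markers (0.0288) and glycolysis (0.041) higher. The arrays lay on 3 slides, each scanned in its own session, of which slide 1 held NZO replicate 12 alone, slide 2 NZO replicate 10 and B6-ob/ob replicate 4, and slide 3 NZO replicate 11 and B6-ob/ob replicates 5 and 6. With slide as a fixed block, as wherever a block is not called random, 2329 genes differed, 1515 higher and 814 lower. Slide 1 holds no B6-ob/ob array, so NZO replicate 12 does not inform the strain difference in that fit. Its lost calls can therefore come from fewer arrays and need not reflect slide. With slide as a random block 3710 genes differed, at a correlation of 0.044 within slides, and all 3643 main calls were kept. Without B6-ob/ob replicate 5 there were 1933. With each array left out in turn, the number of higher members ran from 1 to 10 for cholesterol synthesis, 2 to 14 for chemokines and cytokines, 1 to 4 for immediate early genes, 3 to 5 for ChREBP targets and 5 to 7 for lipogenesis. It ran from 9 to 20 for extracellular matrix, 3 to 8 for macrophages, 4 to 8 for lymphocytes, 2 to 5 for endothelium and 8 to 13 for dedifferentiation genes. In lists that camera did not call it ran from 3 to 6 for fatty acid oxidation, 2 to 5 for glycolysis, 3 to 8 for apoptosis and 3 to 7 for interferon-induced genes, while the number of lower interferon-induced genes ran from 2 to 6. Log2 differences within slide 2 and within slide 3, which share no array, correlated over 16418 genes with r = 0.766.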

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

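Settings with the acinar mean as a covariate, the value table columns as labelled, and 2 arrays left out together were chosen after seeing the data. No paired analysis was possible because the strains share no replicate number, and slide served as a block. Leaving out saturated probes was void, since none was saturated. The count of 3643 genes moved by over 1.5 times to 2329 with slide as a fixed block (814 lower), 1843 within slide 3 (1334 higher, 509 lower, with 1 NZO array assumed to vary like the 2 B6-ob/ob arrays), 8590 with array weights (4307 higher, 4283 lower) and 90 with the acinar covariate (41 higher, 49 lower, 90 by at least 1). That covariate runs almost along the strains, so few calls were possible by construction. With every probe as a feature 2536 were lower, and with normexp and quantile the number of genes that differ by at least 1 on the log2 scale was 962. Leaving out 1 array gave 1933 to 3574 genes, 1298 to 2217 higher and 635 to 1560 lower, 1559 to 2186 by at least 1, and 12 to 17 lists. Low ends followed the loss of B6-ob/ob replicate 5 (1933), NZO replicate 11 (2137) and NZO replicate 10 (2323), and the cause was not tested beyond the loss of an array. Of the main calls 3085 were shared with normexp and quantile normalisation, 3377 with median scaling and 3286 with the value table. With the value table's columns as labelled every sign turns, with 1649 genes higher and 2069 lower in NZO.

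None of the 14 called lists was called with an estimated correlation (0), and of 42 tested lists fry called 37 for change in either direction and 16 for change in one. The endothelial median turned to -0.094 with the acinar covariate. Among named genes these changed sign, none with a call after the change. Ins2 took 0.000, Gcg -0.236 and Ppy -0.078 with normexp and quantile normalisation, and Gcg -0.180 and Ppy -0.043 with quantile normalisation. Ins1 took -0.009 and Ins2 -0.019 with median scaling. The value table gave Apaf1 -0.071, Gcg -0.151 and Ppy -0.034. Nnt took 0.002 with slide as a block, and within slide 3 Pdx1 took -0.174, Txnip -0.332 and Nnt 0.036. The acinar covariate gave Ins1 -0.132, Ins2 -0.600, Gcg -0.210 and Ppy -0.151. With 2 arrays left out, B6-ob/ob 6 and NZO 12, Ins2 took -0.001. Leaving out 1 array gave ranges that cross 0, for Ins1 from -0.026 to 0.147, Ins2 from -0.041 to 0.222, Pdx1 from -0.034 to 0.319 and Nnt from -0.173 to 0.070. The cause was not tested. Apaf1, called in the main setting, lost its call in the value table. Of the other comparisons of a named gene with an alternative, 2189 kept direction and side of the threshold or, with no test, stayed within 1 SD, 229 lost the call, 5 gained it and 59 moved in size. Low signal over background limits the genes not measured in 1 strain, which have bounds only.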

Other observations

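Tests of acinar and stromal markers, of B6-ob/ob replicate 6 and of list calls over other divisions of the arrays were chosen only after the results were seen. Those of gene calls over other divisions, of other probes and of neighbouring genes were set before.

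Genes of the primary cilium, the organelle that Ttc8 serves, leaned lower in NZO, with 4 of 36 called lower and 2 higher. Called or not, 26 differed below 0 and 10 above, with a median of -0.22 (camera adjusted p = 0.0636, fry adjusted p = 0.00638). Ift57 at -0.87, Ift74 at -0.70 and Bbs7 were lower. The list was called lower with the mean of probes (camera adjusted p = 0.0384), no filter (0.0107), array weights (0.045), in the value table (0.0496) and without NZO replicate 12 (0.0421). Genes of oxidative stress defence were mixed, with 4 of 30 higher and 4 lower, Gsta4 at least 6.23-fold higher and Gclc at -0.76 lower. Of 22 apoptosis genes 5 were higher and 1 lower, with Casp12 at 2.15, Bcl2l11 at 0.92 and Apaf1 at 0.75 (camera adjusted p = 0.0609). This list was called higher under normexp and quantile (0.0266), with no filter (0.0423), probes above background on all 6 arrays (0.0334) or every probe (0.0202), and without NZO replicate 11 (0.0493) or B6-ob/ob replicate 6 (0.038). The hypoxia list had 5 of 19 higher and 1 lower, with Egln3 at 3.38 (camera adjusted p = 0.276), and 3 of 12 heat shock genes were higher, with Bag3 at 1.29, Hspb1 at 0.89 and Dnaja1 at 0.58 (camera adjusted p = 0.0581). The heat shock list was called higher with slide as a block (0.0339, with 1 gene higher), array weights (0.00475), no filter (0.0277) or probes above background on all 6 arrays (0.0334), and without NZO replicate 12 (0.033) or B6-ob/ob replicate 6 (0.0207). Among 58 mouse counterparts of human type 2 diabetes genes 5 were higher and 4 lower, with Notch2 at 2.30, Kcnq1 at 2.35 and Arap1 at -1.52 (camera adjusted p = 0.981), and with each array left out in turn 3 to 6 were higher and 1 to 6 lower. Of 28 genes of the unfolded protein response 1 was higher and 1 lower (camera adjusted p = 0.0967). This list was called lower, with 5 genes lower in each, under normexp and quantile (camera adjusted p = 0.0175), quantile normalisation (0.0225) and without B6-ob/ob replicate 6 (0.000541). It was also called in the value table (0.0393), with no filter (0.0192) and with array weights (0.029). Of 31 genes of oxidative phosphorylation 2 were lower (camera adjusted p = 0.0903), or 5 with a call under normexp and quantile (0.0415) and quantile normalisation (0.038). That call was also gained with no filter (0.0176) and without B6-ob/ob replicate 6 (0.00118). None of 30 ribosomal protein genes was called (camera adjusted p = 0.329), while their list was called higher without B6-ob/ob replicate 4 (0.0136). The median of that list was -0.14 within slide 2 and 0.46 within slide 3. Among 16 genes of beta cell adaptation in pregnancy Cldn8, at least 7.36-fold, and Cish at 2.02 were higher and Igfals at -1.17 was lower (camera adjusted p = 0.981).

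In 10 divisions of the 6 arrays into 3 and 3, the real one gave 3643 genes and the highest other 0, and 1 of 10 gave as many. For lists the real one gave 14 and the highest other 17, and 4 of 10 gave as many. With 10 divisions a share under 0.05 cannot be reached. Every other division puts arrays of both strains into each group, so strain differences widen the spread within the groups and lower the gene count. Part of the strain difference also stays between those groups, so these counts do not show what chance alone gives.

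Higher acinar and stromal markers in NZO could come from a lower share of endocrine cells, which was taken to raise markers of all other cells alike. The acinar median exceeded the endothelial one by 2.27 (95% bootstrap interval over genes 1.67 to 2.51), so these lists did not rise alike. Added exocrine tissue would also lower the endocrine share without raising both lists alike, so this comparison cannot decide on that share. The interval reflects the choice of genes and not the spread between samples. Exocrine tissue carried along in different amounts is a candidate source. Within the strains 90.8% of the variance of the acinar markers lay on 1 component, at percentile 99.8 of 1000 lists matched on level, whose median was 73.5%. The matched lists hold unrelated genes, so any list whose genes vary together would rank high. The correlation that camera estimated was 0.846 for acinar markers, 0.921 for ribosomal protein genes and 0.941 for proliferation genes. This rank therefore cannot tell tissue amounts from other reasons to vary together. The 10 most abundant acinar markers differed by 1.83 to 2.89. A strain difference in acinar gene expression or in tissue structure was not tested and stays open.

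Proliferation genes were low on B6-ob/ob replicate 6 and high on replicates 4 and 5. A wrong label with NZO RNA is argued against by 143 genes that part NZO from replicates 4 and 5 by at least 3 on the log2 scale, of which replicate 6 lay nearer to B6-ob/ob at 94.4%. Weak hybridisation is argued against by 24404 probes well above background, within the 23621 to 24711 of the other arrays. Fewer dividing cells outside the islets may lower these genes. The median drop of the proliferation genes exceeded that of the acinar and stromal markers by 2.09 (interval over genes 1.27 to 3.21), so they did not fall alike. The acinar and stromal markers do not count dividing cells, and the drop rests on 1 array, so this comparison cannot decide on that explanation. Differences between animals in the time or extent of beta cell division were not tested and stay open.

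Genes many times lower in NZO by 1 probe might reflect sequence differences under that probe, since the probes were designed on a B6-based genome. Of 50 other kept probes of genes lower by at least 2 on the log2 scale, 76.0% were lower by at least 1, against 87.4% of 135 other probes of genes higher by at least 2 (Fisher's exact test, two-sided, p = 0.0697). Sequence differences and absent transcripts cannot be told apart for these genes, since few have a second kept probe.

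Genes that differ by at least 2 on the log2 scale formed 81 neighbouring pairs with the same direction, against a median of 27 and a highest value of 46 in 10000 shuffles (permutation test, p = 1e-04, one-sided, the smallest these can give). Of the 81 pairs 72 were higher in NZO and 27 had symbols with a common stem, as in the Klk1b, Reg and Prss families.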
